A study of Rattus norvegicus with 10 samples.

How the data were processed

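ATAC-seq libraries from abdominal white adipose tissue (5) and gastrocnemius muscle (5) of Fischer 344 rats were analysed from the peak list of each library, 10 lists in all. The design text speaks of 9 samples per tissue; the others were not analysed here. About 75000 nuclei were tagmented per library, per the labels' protocols. FastQC, Trimmomatic, Bowtie2, Picard and MACS2 and the build rn6 are named per the submitters' processing notes, without versions or settings. Whether reads were shifted for the transposase, and how duplicates and mitochondrial reads were treated, is not given in the sources used here.

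The lists are in narrowPeak layout and were called per library. Each deposited row gives a score, which equals 10 times the −log10 p cut to a whole number in nearly all rows, a fold enrichment at the summit over the caller's background, and the −log10 p and −log10 q of the peak, all by the authors. The fold values were used to rank and describe peaks within a list, and their spacing to read relative depth; fold values of different libraries were set side by side as descriptions and not tested as accessibility. Rows that share an interval and differ in summit were counted as 1 peak, leaving between 164283 and 259149 peaks per library. The peak numbers run in order of p. They end at 300000 or 299999 in adipose, with a lowest −log10 p of 3.26 to 4.27, and in muscle the lists run down to a −log10 p of 2.00. Between 880 and 1361 numbers per list are missing, by a filter that is not stated. The adipose lists are thus cut short by length and the muscle lists by p, which bears on each count made from the deposited lists. Strong peaks, with a −log10 q of at least 5, lie above both limits and were counted beside them. Depth was read from the spacing of the fold values, which gives the caller's background per library; it is relative and carries no read total, so no counting interval is given.

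Peaks of all libraries were merged into regions where they overlapped by at least 1 bp on the placed nuclear chromosomes, and a region was called in a library with a peak in it. Regions called in at least 2 libraries were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment. Library measures were compared with two-sided exact permutation tests of 5 against 5 libraries, and similarity with a one-sided exact permutation of the tissue labels over the mean Jaccard index. Named regions are the 5 exclusive regions per tissue whose worst percentile of fold enrichment over the 5 libraries is best. The regions, the tests on them, the threshold of 5, the set of the 50000 strongest peaks per library, the 50% cover, the 500 bp around summits and leaving out each library were fixed before the data were examined.

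Promoters, genes, gene lists and motifs had also been planned. They need an annotation or genome of rn6, and the gene table at hand is for another assembly, so they are not analysed here and no gene is named. In their place, chosen after seeing the data, peaks were counted in windows of 100 kb on the autosomes and tested with limma (lmFit and eBayes with trend) on log2(peaks per 100000 peaks of the library + 0.5), for windows with a mean of at least 1, with adipose minus muscle as the difference. Named windows follow the rule set for genes: the 10 largest differences in each direction with an adjusted p under 0.05 and no overlap between the tissues. Strong-peak windows were chosen by this rule on strong peaks, except that overlap was judged on peak numbers not scaled to the library. A fitted difference for a window at 0 in a tissue depends on the added 0.5. For single windows of this kind only peak numbers and the adjusted p are given, and fitted differences appear only as ranges over the named windows. Also added after seeing the data were a common −log10 p floor of 4.27, the autosomes alone, adipose replicates 1 and 5 alone, strong regions with no deposited peak in the other tissue, windows of 500 kb, shares per chromosome, the strong share of exclusive regions and of all peaks, strong peaks with single libraries left out, counts over pairs of libraries and the sign-flip test over same-numbered pairs.

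The window test was tested on simulated data with 200 changed windows among 23849, with Poisson counts around each window's mean. It recovered 31.4% of those changed 2-fold and 84.2% of those changed 4-fold, with 4 false calls. Simulated libraries of a tissue differed by Poisson noise and list size alone. Far fewer windows were changed than the 10159 and 7403 called in the real lists. The 4 false calls are therefore no measure of false calls in the real lists. The region code, tested on planted regions, returned 300 of 300 adipose-exclusive, 500 of 500 muscle-exclusive and 400 of 400 shared ones. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used. The titles number the rats 1 to 5 in both tissues; whether a number stands for the same animal is not stated in the labels, so the main tests are unpaired. Coordinates are 1-based on rn6.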

Results

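Open chromatin was profiled by ATAC-seq, in which a transposase cuts accessible DNA in isolated nuclei, in abdominal white adipose tissue (5 libraries) and gastrocnemius muscle (5 libraries) of Fischer 344 rats labelled male and 8 months old. The series compares chromatin accessibility between these tissues. The design text says that samples came from single animals or from tissue pooled over 15 animals, without saying which libraries are which, so p-values measure the spread between these libraries, part of which may be technical. Each library came with its own list of peaks on build rn6, and a peak here is a distinct listed interval. Read totals were not given in the sources used here. The peak caller's background, which scales with depth, gave a relative depth of 0.930 ± 0.210 in adipose and 1.07 ± 0.156 in muscle (SD, n = 5 each, exact permutation p = 0.254), with single libraries between 0.719 (adipose replicate 1) and 1.25 (adipose replicate 4). No annotation of this build was used, so regions are named by position and not by gene.

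Adipose lists held more peaks, and narrower ones, whereas strong peaks covered more sequence in muscle. An adipose library listed 249508 ± 5722 peaks and a muscle library 174456 ± 9101 (SD, n = 5 each), a ratio of 1.43 (two-sided exact permutation p = 0.00794, the smallest this design allows). The peaks covered 87.2 ± 3.87 Mb in adipose and 73.9 ± 2.96 Mb in muscle (n = 5 each, exact permutation p = 0.00794), a difference of 13.3 Mb that was 10.1 Mb at a −log10 p floor common to all lists (exact permutation p = 0.119). Median peak width was 268 ± 17.5 bp in adipose and 312 ± 20.0 bp in muscle (n = 5 each, exact permutation p = 0.00794). Among peaks with a −log10 q of at least 5 the order turned: 80787 ± 16656 peaks in adipose and 99718 ± 12039 in muscle (n = 5 each, exact permutation p = 0.0476), covering 43.3 ± 8.52 and 56.2 ± 4.95 Mb (exact permutation p = 0.00794). With single libraries left out, the mean number of strong peaks stayed higher in muscle in all 10 cases, but the exact permutation p rose above 0.05 in 6. The difference, adipose minus muscle, was -11874 without adipose replicate 1 (exact permutation p = 0.103) and -13978 without muscle replicate 5 (exact permutation p = 0.119). It was -19497 and -19303 without adipose replicates 2 and 5 and -18873 and -19126 without muscle replicates 1 and 3, close to the -18931 of all libraries, with an exact permutation p of 0.0794 each. That in covered length kept an exact permutation p of at most 0.0317. The adipose lists ended at rank 300000 and the muscle lists at a −log10 p of 2.00, so the lists do not share a threshold. The titles number the rats 1 to 5 in both tissues, and with libraries paired by that number the deposited differences had an exact sign-flip p of 0.0625, the smallest that 5 pairs allow.

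**Figure D1:**
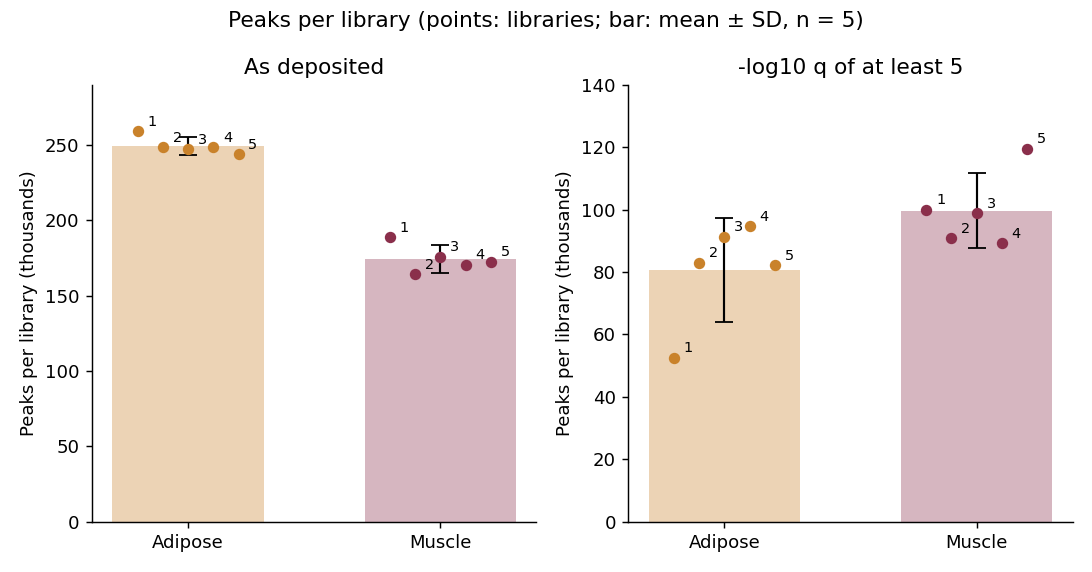
Peaks per library, in units of 1000 peaks, for the lists as deposited (left) and for peaks with a −log10 q of at least 5 (right). Points are libraries with their replicate numbers, bars are means and whiskers are SDs (n = 5 per tissue). The adipose mean is the higher one on the left (249508 against 174456) and the lower one on the right (80787 against 99718), where adipose replicate 1 has 52560 peaks.

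Libraries of the same tissue shared more called sequence than libraries of different tissues, and muscle libraries resembled one another more than adipose libraries did. The Jaccard index, the shared length over the joint length of a pair of peak sets, averaged 0.553 among muscle pairs (range 0.525 to 0.575), 0.296 among adipose pairs (0.247 to 0.333) and 0.253 between tissues (0.205 to 0.299). The mean within tissues exceeded that between tissues by 0.171 (one-sided exact permutation p = 0.00794, the smallest possible). The ranges of adipose pairs and of pairs between tissues overlapped in the deposited lists. At a −log10 q of at least 5 they did not, with means of 0.639 for muscle, 0.430 for adipose (lowest 0.373) and 0.323 between tissues (highest 0.362).

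Regions called in every muscle library and in no adipose library outnumbered the opposite kind. Merging all peaks gave 802351 regions, of which 465777 (58.1%) were called in 1 library. Of these single-library regions, 376248 were from adipose and 89529 from muscle. Among the 336574 regions called in at least 2 libraries, 41378 (12.3%) were called in all 10, 19185 (5.70%) were muscle-exclusive (all 5 muscle libraries and no adipose library) and 5860 (1.74%) were adipose-exclusive. Muscle-exclusive regions covered 12.2 Mb and adipose-exclusive regions 4.18 Mb. An exclusive region had a Fisher's exact p of 0.00794, and its Benjamini-Hochberg adjusted p was 0.107, so 0 regions passed an adjusted threshold of 0.05, although 55403 had an unadjusted p under it. At a −log10 q of at least 5 the adjusted p was 0.0483, so that all 2033 adipose-exclusive and 21234 muscle-exclusive regions passed Fisher's exact test. Leaving out an adipose library asks for 4 adipose libraries in place of 5 and raised the adipose-exclusive count by construction, to 8805, 8152, 8303, 7780 and 7750 without replicates 1 to 5. At a −log10 q of at least 5 it rose to 3609 without adipose replicate 1 and to between 2318 and 2554 without another adipose replicate. With a peak asked for in 2 given libraries of a tissue in place of 5, and still in none of the other tissue, the order turned, to medians of 29712 adipose and 27774 muscle regions over 10 pairs of replicate numbers, with more in adipose for 6 of them.

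**Figure D2:**
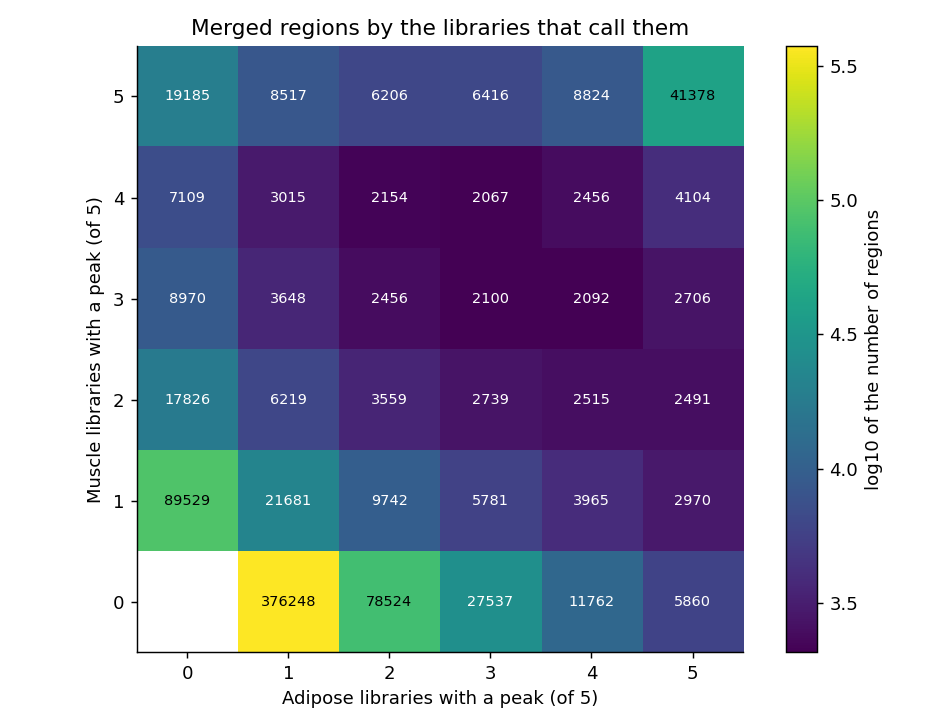
Number of merged regions by how many adipose libraries (horizontal axis, 0 to 5) and muscle libraries (vertical axis, 0 to 5) call them, with colour on a log10 scale. The 19185 muscle-exclusive regions are at the top left, the 5860 adipose-exclusive regions at the bottom right, and the 41378 regions called in all 10 libraries at the top right.

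Exclusive regions ranked above the middle of their lists, with a median percentile of 71.0 ± 1.76 in adipose and 66.3 ± 1.40 in muscle (SD, n = 5 each). This is partly built in, since a region took the rank of its strongest peak and had to be called in all 5 libraries. Regions called in all 10 libraries ranked higher, at 89.7 ± 0.523 in adipose and 81.0 ± 1.53 in muscle. In the muscle libraries 85.1 ± 4.55% of muscle-exclusive regions reached a −log10 q of 5, and in the adipose libraries 56.0 ± 10.1% of adipose-exclusive regions did (SD, n = 5 each, exact permutation p = 0.00794). The tissues differed in this share over all peaks too, at 57.2 ± 6.92% in muscle and 32.5 ± 7.12% in adipose (exact permutation p = 0.00794) with a ratio of 1.76 against 1.52 for exclusive regions. Regions called in all 10 libraries reached it in 93.3 ± 3.30% and 88.1 ± 8.38% of cases. Fold enrichment is the authors' own value and was used to rank peaks within a list. The muscle-exclusive region with the best worst rank was on chromosome 18 at 8074557 to 8075257, with a fold enrichment of 24.3 ± 1.44 over the 5 muscle libraries. It was followed by regions on chromosome 17 at 24331369 to 24332224 (24.9 ± 2.97), chromosome 18 at 59367239 to 59367885 (24.9 ± 2.91), chromosome 11 at 51739280 to 51740139 (24.3 ± 2.33) and chromosome 4 at 40786146 to 40787225 (24.1 ± 2.22). The adipose-exclusive regions chosen in the same way were on chromosome 10 at 50724609 to 50725622 (8.59 ± 1.24), chromosome 18 at 3134028 to 3134826 (8.97 ± 1.80), chromosome 2 at 263932185 to 263933155 (8.62 ± 1.21), chromosome 7 at 70421934 to 70422663 (8.45 ± 1.07) and chromosome 4 at 49515795 to 49516673 (8.92 ± 1.56). Their lowest percentile in any adipose list was 94.8, and that of the named muscle regions in any muscle list was 99.2.

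Windows of 100 kb along the autosomes differed widely in how many peaks the tissues had in them. Of 23849 windows tested with limma on log2 peaks per 100000 peaks of the library, 10159 had more peaks in adipose and 7403 had more in muscle at a Benjamini-Hochberg adjusted p under 0.05. Muscle windows thus made up 42.2% of the calls. The median log2 difference over all windows was 0.26 towards adipose. Without scaling to the library's number of peaks, 13527 windows had more peaks in adipose and 3808 in muscle. At a −log10 q of at least 5 the counts were 3892 and 4124, with 3563 muscle calls and 2532 adipose calls shared with the deposited lists and 233 calls opposite, among 17518 windows tested in both.

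The window with the largest fitted log2 difference towards muscle was on chromosome 10 at 53700001 to 53800000, with 38.0 ± 2.35 peaks in a muscle library and 0.60 ± 0.894 in an adipose library (SD, n = 5 each). Its log2 difference, adipose minus muscle, was -5.05 (SE 0.26, limma adjusted p = 3.99e-10) with 0.5 added to the peaks per 100000, and -4.27 with 1 added, and 2 of the 5 adipose libraries had a peak there. Larger differences in the number of peaks were found in adjacent windows on chromosome 3. Those from 63600001 to 63700000 and from 63700001 to 63800000 had 45.4 ± 5.86 and 50.6 ± 4.67 peaks in muscle against 2.60 ± 2.51 and 5.6 ± 1.52 in adipose. On chromosome 12 at 46200001 to 46300000 there were 19.8 ± 5.93 peaks in muscle and 0.400 ± 0.894 in adipose. A run of 3 windows on chromosome 10 from 8300001 to 8600000 had 16.6 ± 7.44, 23.4 ± 3.78 and 25.0 ± 4.06 peaks in muscle and 1.00 ± 1.22, 2.00 ± 2.55 and 1.60 ± 1.82 in adipose. The remaining windows named for muscle were on chromosome 10 at 45400001 to 45500000 (36.2 ± 5.02 against 2.60 ± 1.52), chromosome 5 at 75900001 to 76000000 (21 ± 2.45 against 1.80 ± 1.79) and chromosome 18 at 78600001 to 78700000 (11.2 ± 2.17 against 0.20 ± 0.447). In the first window 22.8 ± 1.92 peaks per muscle library (60.0%) reached a −log10 q of 5, and none did in any adipose library. The strong share of the muscle peaks was 39.2% to 66.1% in 8 of the 10 windows named for muscle, and 16.2% and 15.7% in those on chromosome 5 and on chromosome 10 at 8300001 to 8400000.

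**Figure D3:**
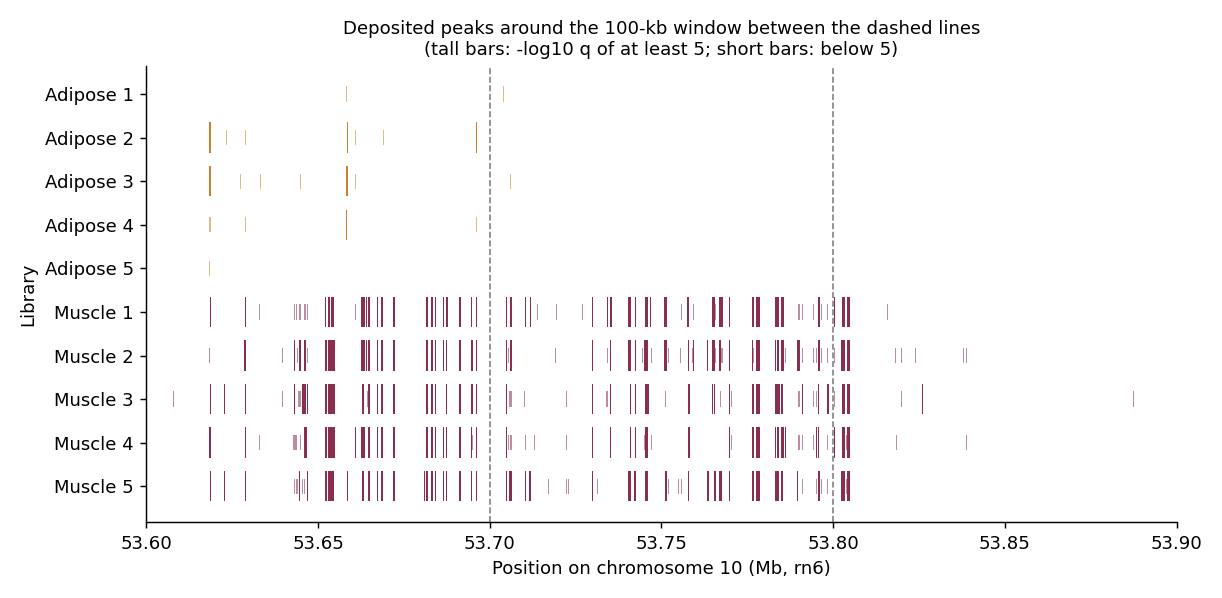
Deposited peaks in each of the 10 libraries on chromosome 10 between 53.6 and 53.9 Mb (build rn6). Tall bars are peaks with a −log10 q of at least 5, short pale bars are weaker peaks, and dashed lines bound the window from 53700001 to 53800000, where muscle libraries averaged 38.0 peaks and adipose libraries 0.60.

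In the 10 windows named for adipose 8.86% to 17.1% of the adipose peaks were strong. The first by fitted log2 difference, on chromosome 3 at 69100001 to 69200000, had 17.2 ± 5.12 peaks in an adipose library and was listed at 0 in each muscle library, but 2.20 ± 2.86 of the adipose peaks reached a −log10 q of 5. Windows on chromosome 16 at 33100001 to 33200000, at 35000001 to 35100000 and at 52200001 to 52300000 had 16.4 ± 4.16, 15.8 ± 2.05 and 15.2 ± 3.03 adipose peaks and were also at 0 in muscle. Across all windows with more peaks in adipose, 16.3 ± 5.92% of the adipose peaks reached that threshold, against 48.7 ± 8.88% of the adipose peaks in windows with more peaks in muscle (SD, n = 5), and the first share was the lower one in each of the 5 libraries. The muscle libraries' own peaks showed the same order, with 37.3 ± 12.1% in windows with more peaks in adipose and 60.2 ± 6.34% in windows with more peaks in muscle, again lower in each of the 5 libraries. Among strong peaks alone, the windows chosen for adipose by the rule for strong peaks were elsewhere. One was on chromosome 2 at 222900001 to 223000000, with 7.40 ± 2.51 strong peaks in adipose and 0 in each muscle library (limma adjusted p = 3.75e-07). On chromosome 14 at 22000001 to 22100000 there were 12.6 ± 5.77 in adipose and 0.60 ± 0.894 in muscle (limma adjusted p = 4.32e-05).

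Chromosomes 10 and 12 took a larger share of the peaks in muscle. Chromosome 10 held 6.25 ± 0.328% of the peaks of a muscle library and 3.57 ± 0.425% of those of an adipose library (SD, n = 5 each, exact permutation p = 0.00794, adjusted p = 0.0139 over 21 chromosomes). Chromosome 12 held 2.66 ± 0.117% and 1.56 ± 0.166% with the same p-values. Chromosome 2 went the other way, with 7.81 ± 0.407% in muscle and 10.4 ± 0.678% in adipose. Among strong peaks the shares moved closer, to 6.71 ± 0.0893% and 5.57 ± 0.496% for chromosome 10 and 7.47 ± 0.0872% and 8.57 ± 0.772% for chromosome 2 (exact permutation adjusted p = 0.0167 each). Of the 20 autosomes, 5 had a larger share in muscle and 5 a larger share in adipose at an adjusted p under 0.05 in the exact permutation tests on both the deposited and the strong peaks. Muscle-exclusive regions followed the same order, at 9.97% of the tested regions of chromosome 10, 8.81% of chromosome 12 and 4.05% of chromosome 2. So did regions called in all 10 libraries. They were 2857 of 14276 tested regions on chromosome 10, 1192 of 6153 on chromosome 12 and 2925 of 33953 on chromosome 2. The order of the exclusive regions is thus not particular to them.

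The sex chromosomes set 3 adipose libraries apart. Adipose replicates 2, 3 and 4 had 3.26%, 2.78% and 3.47% of their peaks on chromosome X and 0, 0 and 1 peaks on chromosome Y. Adipose replicates 1 and 5 had 1.07% and 1.45% on X with 31 and 45 Y peaks, and muscle libraries had 1.41% to 1.74% on X with 16 to 24 Y peaks. Among strong peaks, replicates 2, 3 and 4 had 1.93%, 1.95% and 2.59% on X and no Y peak, replicates 1 and 5 had 1.47% and 1.54% on X with 6 and 13 Y peaks, and muscle libraries had 1.73% to 1.91% on X with 11 to 14 Y peaks. All 10 libraries are labelled male. With adipose replicates 1 and 5 as the only adipose libraries there were 30321 adipose-exclusive and 28551 muscle-exclusive regions, a setting that asks for fewer adipose libraries by construction, and 7096 windows had more peaks in adipose and 6714 in muscle. On the autosomes alone the exclusive counts were 5793 and 18757.

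**Figure D4:**
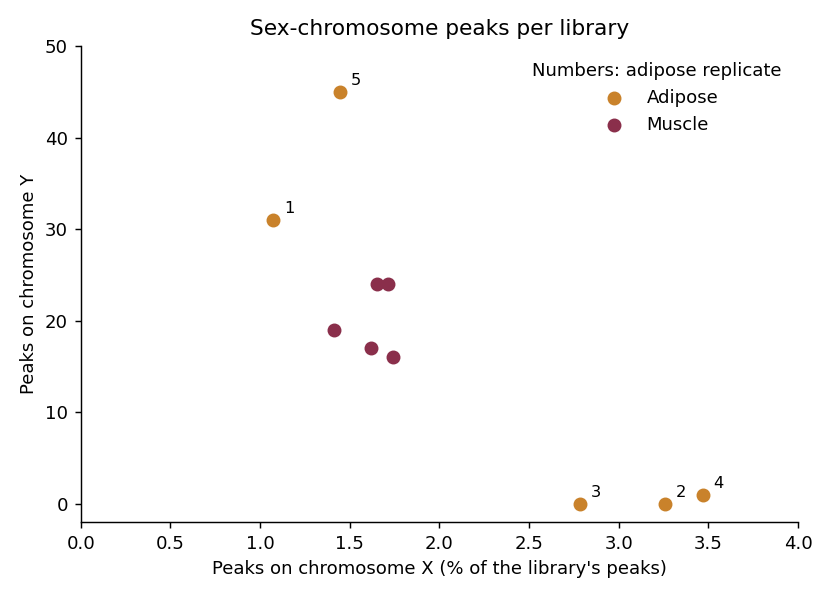
Share of each library's peaks on chromosome X (horizontal axis, %) against its number of peaks on chromosome Y (vertical axis), with 1 point per library and adipose replicates numbered. Adipose replicates 2, 3 and 4 lie at 2.78% to 3.47% with at most 1 Y peak, and the other libraries lie at 1.07% to 1.74% with 16 to 45 Y peaks.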

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

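Within each tissue, the highest and lowest of the 5 libraries were compared with their nearest neighbour, and 15 values stood apart by more than 0.71 of the range. The test was run on 100 sets of 5 libraries, and chance alone sets off about 1 in 20. The values are given without an explanation.

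Muscle replicate 4 covered 68.6 Mb, the least among muscle libraries. Adipose replicate 1 covered 28.5 Mb with strong peaks, the least among adipose libraries. Muscle replicate 5 had the highest median fold enrichment in muscle, at 4.10. Chromosome 1 took 11.9% of the peaks of muscle replicate 3, the highest share in muscle, and chromosome 11 took 3.23% in muscle replicate 2, also the highest. Muscle replicate 1 had the lowest muscle shares on chromosome 8 (5.21%), chromosome 10 (5.67%) and chromosome 12 (2.46%). Adipose replicate 4 had the lowest adipose share on chromosome 3, at 6.23%.

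In the named windows the values that stood apart were small numbers of peaks. Muscle replicate 1 had 1 peak on chromosome 4 at 74000001 to 74100000 and muscle replicate 2 had 1 on chromosome 2 at 73500001 to 73600000, where the other muscle libraries had 0. Adipose replicate 3 had 2 peaks on chromosome 12 at 46200001 to 46300000 and adipose replicate 5 had 1 on chromosome 18 at 78600001 to 78700000, where the other adipose libraries had 0. Adipose replicate 1 had 0 on chromosome 10 at 45400001 to 45500000, below the other adipose libraries. The exclusive muscle region on chromosome 18 at 59367239 to 59367885 had its highest fold enrichment, 30.0337, in muscle replicate 5.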

How the results depend on the processing

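The alternatives for windows, the common floor, adipose replicates 1 and 5 alone, the strong peaks with single libraries left out and the replicate block on library measures were chosen after seeing the data. Similarity of peak sets stayed on its side of the threshold in every setting run. The adipose minus muscle difference in peaks turned to -18930.6 at a −log10 q of at least 5, and that in covered length to -12.8 Mb there and to -5.18 Mb for the 50000 strongest peaks; at the common floor it was 10.1 Mb (exact permutation p = 0.119). The cause was not tested. Among strong peaks with single libraries left out, these ranged from -22425.6 to -11873.8 peaks, with an exact permutation p above 0.05 in 6 of 10 cases. Adipose-exclusive regions numbered 2033 at a −log10 q of at least 5 (2092 to 3609 there with single libraries left out), 3591 for the 50000 strongest peaks, 3227 with 50% cover and 1019 when strong and without any deposited peak in muscle. They ranged from 6162 to 8805 with single libraries left out, and were 30321 with adipose replicates 1 and 5 alone, by construction. Muscle-exclusive regions numbered 12212 for the 50000 strongest peaks and 12629 when strong and without any deposited adipose peak. Windows with more peaks in adipose and in muscle numbered 3892 and 4124 at a −log10 q of at least 5, 3669 and 3829 for the 50000 strongest peaks, and 2299 and 1903 of 5197 windows of 500 kb, which are fewer by construction. Without scaling, 3808 had more in muscle. Named windows were tested in 349 of 360 pairs of window and alternative and kept their call in those. In the other 11 the window fell under the filter on peaks: 9 of the 10 adipose windows and 1 muscle window for the 50000 strongest peaks, and 1 adipose window at a −log10 q of at least 5. The log2 differences of the adipose windows, 3.70 to 3.86, were 1.82 to 2.82 at that threshold (highest limma adjusted p = 0.0479) and 2.82 to 2.96 with 1 added in place of 0.5. Those of the muscle windows, -5.05 to -3.45, were -5.58 to -2.49 and -4.27 to -2.80. The named windows were chosen for large differences without overlap between the tissues. Most alternatives reuse the same peaks, so a kept call was largely fixed by that choice. Named regions kept their call in 47 of 50 alternatives, and 3 lost 1 library. These regions were chosen for a high rank in every list of their tissue. Settings that keep fewer of the same peaks cannot add a peak in the other tissue, so this outcome was largely fixed by the choice. The titles number the rats 1 to 5 in both tissues, without saying that a number is the same animal. Pairing was looked for in 289371 autosomal regions called in at least 2 but not all 10 libraries, as deviations from each region's mean per tissue. In these deviations same-numbered libraries correlated between -0.00368 and 0.0130. No adipose library correlated best with its own number there, so pairing is not shown by the data. Adipose replicates 2, 3 and 4 listed 0, 0 and 1 Y peaks, and muscle replicates 2, 3 and 4 listed 17, 24 and 24. If Y peaks follow the animal, these numbers do not stand for 1 animal in both tissues. With the replicate block, 10093 and 7342 windows were called, and the differences of 75051.4 peaks and 13.3 Mb had an exact p of 0.0625, the smallest that 5 pairs allow. Promoter, gene, gene list and motif alternatives were not run. Depth is known only relative between libraries, so windows with few peaks are limited by the caller.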

Other observations

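Muscle-exclusive regions lay closer together than regions drawn at random from all tested ones. There were 798 windows of 100 kb with at least 5 of them, against a mean of 125 and a highest value of 159 in 1000 shuffles of the exclusive regions among the tested ones of each autosome. The densest window held 18 and was on chromosome 10 at 53700001 to 53800000. The tested regions include those called in adipose libraries alone, and no other set of muscle-called or shared regions was shuffled. The shuffles thus cannot tell whether the clustering is particular to exclusive regions. Adipose-exclusive regions reached 5 or more in 3 windows, against a shuffled mean of 0.553 and a highest value of 4. Their count was thus above the shuffled mean and within the range of the shuffles. With so few windows, the shuffles cannot decide whether adipose-exclusive regions cluster as well.

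The tests that follow were chosen after the results were seen, except the recurrence of weak peaks and the shares of single autosomes.

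Adipose lists held more peaks than muscle lists. The adipose lists stop at a higher −log10 p than the muscle lists, so their length limit can only lower the adipose counts and could not produce the excess. At a common −log10 p floor the ratio of mean peaks was 1.49 with no overlap between the tissues. Depth does not account for the excess either, since the caller's background in adipose was 0.869 times that in muscle. Weak adipose peaks recurred in another adipose library at least 3.82 times as often as the same peaks moved at random, so they are not all chance background. That ratio covers weak peaks as a whole and not the excess, of which 76.3% lay in peaks that no other library of the tissue called, so chance background may account for much of it. Peaks particular to 1 animal would look alike, and a difference between the tissues stays open.

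Adipose replicates 2, 3 and 4 have more X peaks and at most 1 Y peak although labelled male. Depth does not account for the missing Y peaks, since the shallower adipose libraries had at least 31. In the deposited lists no autosome's largest share among adipose libraries exceeded its smallest by more than 1.37 times, against 3.23 for X. A library difference acting on all chromosomes alike would not give this, but the comparison cannot exclude one that acts on X in particular. Among strong peaks the X shares lay closer, at 1.93%, 1.95% and 2.59% in adipose replicates 2, 3 and 4 and 1.47% and 1.54% in adipose replicates 1 and 5. For the X share depth stays open, because the 4 other libraries of like depth (X share up to 1.74%) were all muscle and the low-X adipose libraries were the shallowest. A candidate explanation is that these libraries came from animals without a Y chromosome, since each of the other 7 libraries had at least 16 Y peaks. How this came about was not tested, and it was found and tested on the same data.

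Of the X regions called in exactly 3 libraries, 243 were called in adipose replicates 2, 3 and 4, and the next set of 3 had 79. These 3 also shared 3795 autosomal regions called in no other library, second to adipose replicates 1, 4 and 5 with 3938 autosomal and 13 X regions.

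Other splits of the 10 libraries into 5 and 5 were drawn, 100 with the real one included. For adipose-exclusive and for muscle-exclusive regions 1 of 100 splits, the real one, gave as many, with 5860 and 19185 regions against at most 351 in the others. For windows it was also 1 of 100, with 17562 called against at most 7107. The real split gave the highest number for all 3 counts, so a chance division of the libraries is an unlikely source of them. With 100 splits, no share below 1 of 100 could be seen. Splitting the libraries does not separate tissue from the limits of the lists, which also follow the tissue. At the common −log10 p floor, which every list reaches, there were 5318 adipose-exclusive and 18308 muscle-exclusive regions. Windows with more peaks in adipose and in muscle numbered 9710 and 6827 there. These values argue against the unequal limits as the source of most of the deposited counts.

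Places were ranked by their lowest −log10 p over the 10 lists, which picks places strong in every list. On chromosome 4 at 77447547 to 77448683 the −log10 p was between 1081 and 9290, and on chromosome 14 at 46329381 to 46330136 between 723 and 3746. On chromosome 20 at 19483938 to 19485278 it was between 666 and 7389. Their fold enrichments were 8.64 to 11.3, 29.6 to 37.5 and 9.28 to 10.6, in the same order. The place with the highest −log10 p was thus not the one with the highest fold enrichment.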
